A study of Homo sapiens with 10 samples.

How the data were processed

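The series holds RNA-seq of 10 cultures of cardiomyocytes made from a wild-type human induced pluripotent stem cell (iPSC) line by modulation of the Wnt pathway. Per the labels, 5 cultures received 1 mM dimethyloxalylglycine (DMOG) and 5 received vehicle for 18 h from day 14, and all were harvested on day 15. DMOG is a cell-permeable mimic of 2-oxoglutarate that inhibits 2-oxoglutarate dependent oxygenases, the HIF prolyl hydroxylases among them. Total RNA libraries were made with a stranded kit, per the labels' protocols. The labels describe the samples as biological replicates without saying whether they came from separate differentiations, so the p-values measure the spread between these samples.

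The authors deposited 1 table with 28235 RefSeq transcript rows. It holds the raw read count of every library per row, and the authors' log2 CPM values (counts scaled to library size), per the file headers; the values fit effective library sizes that differ from the column totals. Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.2.1.0, SAMtools 0.1.19.0 and edgeR were used with build hg19 (GRCh37). The counter, the annotation version and whether counting used the strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. The same holds for genes with near-identical copies, which include the histones, the ribosomal proteins and, among single genes named, CRIPTO and PSME2. The table appeared filtered before deposit, since every row exceeded 1 CPM on the deposited scale in at least 3 libraries. It holds 0 rows of mitochondrially encoded genes, so the planned results on them were not analysed here.

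Symbols were matched to 27554 rows through the RefSeq accessions of the GRCh38.p14 gene table and to 276 further rows through GENCODE v29. The 405 rows left kept their accession. No coordinates are given because that assembly is not the build of the counts. Y-linked genes, those shared by X and Y, XIST and TSIX were left out, which left 28129 rows. Isoforms of a gene overlapped in the table, and the rows summed to 2.03 to 2.07 times the counts of 1 row per gene. The transcript row with the highest mean CPM therefore stood for its gene, a choice made after the table was examined. This gave 14539 genes, of which 8377 had 1 row and 6162 had more. Library totals over these genes ranged from 48601530 to 196387627 counts.

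The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. TMM factors, filterByExpr (which removed 0 genes), robust dispersions and the quasi-likelihood F test were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Rose", "fell" and "called" refer to this test. The SE of a log2 fold change is its size divided by the square root of F. Counts were simulated for this comparison over 14539 genes. The test recovered 30.3% of 66 genes changed by 0.5 on the log2 scale. It recovered 77.6% of 67 changed by 1 and 95.5% of 67 changed by 1.5, with 4.43% false discoveries. With so few genes changed, the adjusted threshold is stricter than in the real comparison, where 8128 were called. The simulation also held no replicate sets, so its recovery and false discovery shares need not hold for these data. The common biological coefficient of variation was 22.9%.

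Before the data were examined, 34 gene lists were fixed, 33 of which had at least 5 tested members. They were tested with camera from limma 3.58.1 at the preset inter-gene correlation of 0.01, with adjustment over the lists. The naming rule was fixed at the same time. It takes the 12 largest rises and 12 largest falls among called genes with a symbol that is not a clone, antisense, small RNA or pseudogene name, a mean log2 CPM of at least 3 and groups that do not overlap. It adds the 4 tested members of each list with the smallest p, and EGLN1, EGLN2, EGLN3, HIF1AN, HIF1A, EPAS1, HIF3A, ARNT and VHL whatever their result. The rule named 152 genes, of which examples are given. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a replicate block, a test against a fold change of 1.5, leaving out each library, and, chosen later, thinning the libraries to the smallest total and leaving HIF targets out of other called lists. Shares of counts were compared by an exact two-sided permutation test over all 252 assignments.

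Within a group no pair of libraries agreed within sampling noise (chi-square per degree of freedom over genes 27 to 385). Deviations from the group means of libraries with the same replicate number correlated across genes at 0.73, 0.75, 0.18, 0.56 and 0.66 for numbers 1 to 5. All lay over 0.1, so the numbers were taken to pair the samples. This pairing comes from the data and not from the labels, and a library correlated best with its own number for 1 of the 5 numbers. Libraries numbered 1 and 2 stood apart from those numbered 3 to 5 in both groups, with a median correlation of deviations of -0.78 across these sets. Within the sets, deviations correlated across the groups at medians of 0.74 (numbers 1 and 2) and 0.49 (numbers 3 to 5). The same-number values can therefore reflect the sets and not pairs. The main test modelled neither pairs nor sets, and the replicate block was an alternative. The labels give no batch. Where the call of a list changed within a set alone, the value in that set is given. The use of transcript rows within genes was compared with limma on the log2 ratio of a row to the highest row of its gene, after adding 1 count to each, for rows with a mean of at least 100 counts that differed from the highest row by a mean of at least 100. A gene's smallest p was multiplied by its number of rows before adjustment. That comparison was chosen after the table was examined. In its simulation over the same 3453 genes, with an assumed noise between libraries of 0.05 on the logit scale, 100 genes were changed by 0.7 on that scale (a median log2 change of -0.15). Of these 100% were recovered, with 7.41% false discoveries. The noise was assumed and not estimated from these libraries, and held no replicate sets, so these shares need not hold for the real rows.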

Results

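RNA-seq counts were compared between 5 cultures of human iPSC-derived cardiomyocytes treated with DMOG, an inhibitor of prolyl hydroxylases and other 2-oxoglutarate dependent oxygenases, and 5 cultures treated with vehicle. The comparison asks which transcripts respond to this inhibition, with protein degradation, protein synthesis and splicing named by the study as processes of interest. Total counts over the genes compared were 81838820, 196387627, 50012475, 49612417 and 68769331 in vehicle replicates 1 to 5, and 48601530, 84040057, 60870418, 80808416 and 65070736 in DMOG replicates 1 to 5.

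DMOG changed the level of 8128 of 14539 genes (55.9%) in edgeR's quasi-likelihood test at an adjusted p under 0.05. Of these, 4082 rose and 4046 fell. More than 2-fold changes numbered 623 upward and 1052 downward. Among genes with a mean log2 CPM of at least 3 and no overlap between groups, the largest rises included NR4A1 (NM_001202233), an orphan nuclear receptor, at a log2 fold change of 3.98 (SE 0.45), NDRG1 (NM_001135242), a hypoxia-responsive gene, at 3.97 (SE 0.19), and the hexokinase HK2 (NM_000189) at 3.37 (SE 0.14). The largest falls there included GJA5 (NM_005266), which encodes the gap junction protein connexin 40, at -3.98 (SE 0.24), and SRL (NM_001098814), which encodes the calcium-binding protein sarcalumenin of the sarcoplasmic reticulum, at -3.22 (SE 0.19). GJA5 went from a mean log2 CPM of 5.33 ± 0.29 (SD, n = 5) to 1.32 ± 0.46. The libraries of both groups did not overlap for 3086 genes that were higher and 3188 that were lower in DMOG, 43.2% of all genes, where chance gives 0.794%.

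The first principal component separated the groups, and the second separated replicates 1 and 2 from replicates 3 to 5 in both groups. Replicates 1 and 2 alone gave 8613 calls, 6926 of them shared in direction with the 8128, and replicates 3 to 5 alone gave 8919, with 7379 shared. The fold change had the same sign in both sets for 99.9% of the 8128 genes. These genes were called from both sets together, so a shared sign was nearly fixed in advance. Neither the shared calls nor the shared signs are independent replication. The 10 most abundant genes held 5.66% ± 0.233 (SD, n = 5) of counts in vehicle and 6.98% ± 0.278 (SD, n = 5) in DMOG, a difference with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 can give. The permutation treats all libraries as exchangeable and ignores the pairing. TMM factors averaged 1.08 ± 0.0102 (SD, n = 5) in vehicle and 0.924 ± 0.0214 in DMOG, and the choice of scaling set the balance of directions. Calls were 50.2% upward with TMM, 36% with upper quartile scaling (2922 higher, 5201 lower) and 27.3% with library totals (2316 higher, 6169 lower). The median of all genes lay at 0.01 with TMM, -0.12 with upper quartile scaling and -0.22 with library totals.

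**Figure D1:**
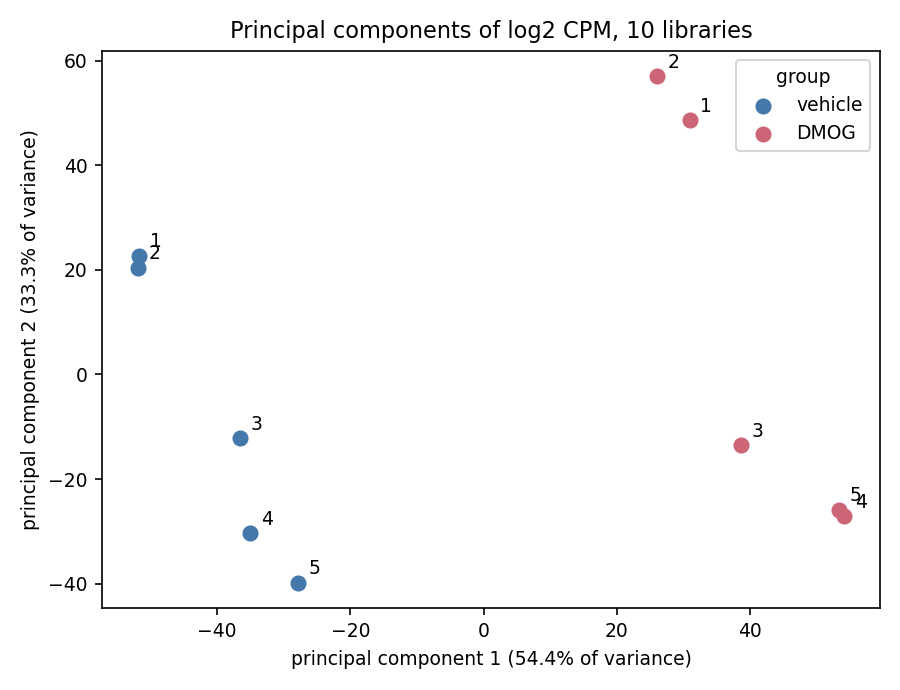
Principal components of log2 CPM over all genes, with the percentage of variance on each axis. Each point is a library numbered by replicate, blue for vehicle and red for DMOG; the horizontal axis (54.4% of variance) separates the groups and the vertical axis (33.3%) separates replicates 1 and 2 from 3 to 5.

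Known targets of the hypoxia-inducible factors (HIF) rose together. Of 47 tested HIF target genes outside glycolysis, 40 rose, 0 fell and 7 did not pass, with a median log2 fold change of 1.76 (camera adjusted p = 1.1e-46). NDRG1 went from a mean log2 CPM of 6.27 ± 0.29 (SD, n = 5) to 10.24 ± 0.29. ANKRD37 rose by 3.66 (SE 0.11) and VEGFA, the angiogenic growth factor, by 3.05 (SE 0.17). Of 30 glycolysis and glucose uptake genes, 26 rose, 0 fell and 4 did not pass, with a median of 0.99 (camera adjusted p = 3.0e-23). PFKFB3, a regulator of glycolytic flux, rose by 2.93 (SE 0.12), and the glycolytic enzyme ENO1 by 1.51 (SE 0.08). Both list calls held with an estimated correlation (adjusted p = 4.6e-04 each). With the replicate block and an estimated correlation neither did (adjusted p = 0.071 each).

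Among the oxygen sensing genes, the prolyl hydroxylase EGLN3 rose by 2.82 (SE 0.11), EGLN1 by 1.66 (SE 0.18) and EGLN2 by 0.57 (SE 0.09). HIF1A mRNA fell by 0.87 (SE 0.07), VHL, the HIF ubiquitin ligase subunit, by 0.45 (SE 0.06), and HIF1AN by 0.33 (SE 0.07). ARNT, the HIF beta subunit, rose by 0.31 (SE 0.06), but its call was lost with library totals (0.08, adjusted p = 0.24, with 3.9e-06 to 0.24 over all alternatives). EPAS1 (0.06, adjusted p = 0.90) and HIF3A (-0.11, adjusted p = 0.53) did not pass. Of 52 tested 2-oxoglutarate oxygenases, the class of enzymes DMOG inhibits, 28 rose, 11 fell and 13 did not pass, with a median of 0.37 (camera adjusted p = 6.7e-07, and adjusted p = 0.11 with an estimated correlation). The collagen hydroxylases PLOD2, P4HA1 and P4HA2 rose by 2.44 (SE 0.07), 3.13 (SE 0.10) and 2.37 (SE 0.14). Of the 28 that rose, 10 also belong to the HIF target list, these 3 among them. Of the other 42 oxygenases 18 rose, 11 fell and 13 did not pass, with a median of 0.12, and without the HIF targets the list was not called (camera adjusted p = 0.23). With library totals 25 oxygenases rose and 16 fell, at a median of 0.14.

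**Figure D2:**
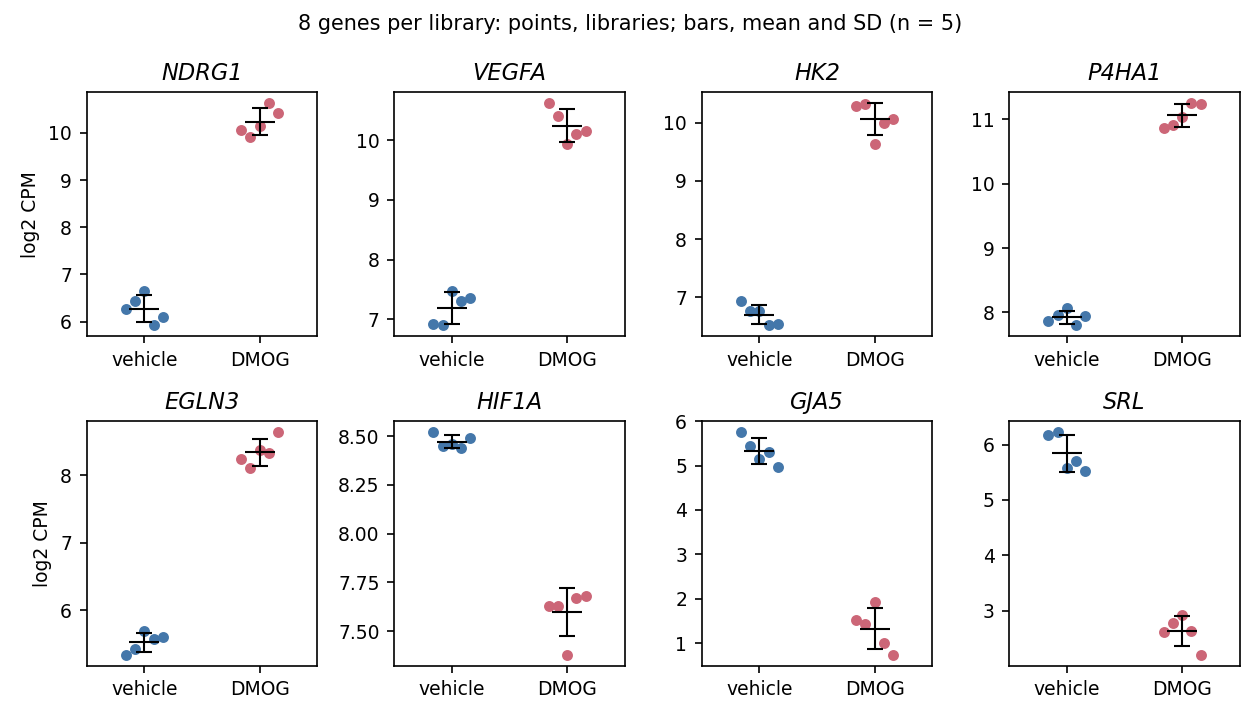
Log2 CPM of 8 genes in each library, with the mean and SD (n = 5) as bars; the vertical scale differs between panels. NDRG1, VEGFA, HK2, P4HA1 and EGLN3 were higher and HIF1A, GJA5 and SRL lower in every DMOG library than in every vehicle library.

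The lists of endoplasmic reticulum chaperones and of amino acid stress genes were called higher at the preset correlation and not with an estimated one. The first list also holds genes of protein degradation and stress signalling, such as SEL1L and ATF6. Of its 30 genes, 26 rose, 2 fell and 2 did not pass, with a median of 0.84 (camera adjusted p = 4.5e-10, and adjusted p = 0.28 with an estimated correlation). DNAJB9, HERPUD1 and SEL1L, which act in endoplasmic reticulum associated degradation, rose by 1.58 (SE 0.13), 1.49 (SE 0.14) and 1.10 (SE 0.11). In the list of aminoacyl-tRNA synthetases and amino acid stress genes, 22 of 39 rose, 2 fell and 15 did not pass, with a median of 0.55 (camera adjusted p = 1.6e-05, and adjusted p = 0.61 with an estimated correlation). ATF4, the transcription factor of this response, rose by 1.28 (SE 0.08) and its target DDIT3 by 3.14 (SE 0.17). Of 29 immediate early genes 14 rose, 1 fell and 14 did not pass, with a median of 0.74 (camera adjusted p = 7.5e-05, and adjusted p = 0.54 with an estimated correlation). FOS rose by 3.12 (SE 0.14). NR4A3 rose by 4.23 (SE 0.35) from a low level, with 33 to 120 counts in vehicle libraries and 419 to 1740 in DMOG libraries. Of 43 genes of MYC, mTOR and growth signalling, 25 rose, 5 fell and 13 did not pass, with a median of 0.41 (camera adjusted p = 3.1e-05, and adjusted p = 0.11 with an estimated correlation). Those that rose included DDIT4, an inhibitor of mTOR, at 2.86 (SE 0.13), and the MYC antagonists MXI1 and MXD1 at 2.2 (SE 0.08) and 2.02 (SE 0.13). With library totals 18 of these growth signalling genes rose and 9 fell, at a median of 0.18, and 17 amino acid stress genes rose and 7 fell, at a median of 0.32.

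Genes of protein degradation moved in both directions. Of 45 ubiquitin ligases and adaptors, 19 rose, 7 fell and 19 did not pass, with a median of 0.19 (camera adjusted p = 0.012, and adjusted p = 0.26 with an estimated correlation). SIAH2, a ligase of prolyl hydroxylases, rose by 1.57 (SE 0.07) and ITCH by 0.79 (SE 0.06). Of 53 autophagy and lysosome genes, 24 rose, 6 fell and 23 did not pass, with a median of 0.18 (camera adjusted p = 0.0085, and adjusted p = 0.41 with an estimated correlation). SQSTM1, the autophagy receptor p62, rose by 1.69 (SE 0.10). With library totals 11 ligases rose and 16 fell (adjusted p = 0.049), and 16 autophagy genes rose and 17 fell, and the autophagy list was not called (adjusted p = 0.051). The ubiquitin ligase list also lost its call with camera on voom values (adjusted p = 0.061) and in replicates 1 and 2 alone (adjusted p = 0.16); the interaction with the replicate set did not pass (adjusted p = 0.70). Of 43 proteasome genes 12 rose, 11 fell and 20 did not pass (camera adjusted p = 0.62), against 1 that rose and 23 that fell with library totals. The proteasome activator genes PSME1, PSME2 and PSME3 fell by 0.65 (SE 0.08), 1.00 (SE 0.07) and 0.72 (SE 0.07). The list of cytosolic heat shock genes also holds the mitochondrial HSPD1 and HSPE1. Of its 32 tested genes 12 rose, 4 fell and 16 did not pass (camera adjusted p = 0.21). With library totals 9 rose and 7 fell, as the median went from 0.18 to -0.06.

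The size of the change in ribosomal protein genes, and its call, depended on the scaling. Of 78 cytosolic ribosomal protein genes 58 rose, 0 fell and 20 did not pass, with a median of 0.22 (camera adjusted p = 0.0015, and adjusted p = 0.95 with an estimated correlation). With library totals 0 rose and 2 fell, at a median of 0.00 (adjusted p = 0.057). With upper quartile scaling 5 rose and 1 fell, at a median of 0.09, and the list stayed called upward (adjusted p = 0.017). Under each of these scalings the median lay 0.21 above that of all genes. A scaling shifts all genes alike, so this distance could not change and is no check. In replicates 1 and 2 alone 12 rose and the list was not called (adjusted p = 0.083), while in replicates 3 to 5 alone 59 rose and 1 fell; the interaction of list and replicate set did not pass (adjusted p = 0.16). After the trend of fold change with expression level was removed, the median was -0.03. Of 48 translation initiation and elongation factors 21 rose, 7 fell and 20 did not pass (camera adjusted p = 0.069), and with library totals 7 rose and 14 fell. This list passed upward without DMOG replicate 1 (adjusted p = 0.038) and with camera on voom values (adjusted p = 0.019), and had an adjusted p = 0.66 with an estimated correlation. EIF4A2 rose by 0.68 (SE 0.06) and EIF4EBP2, a repressor of cap-dependent translation, fell by 0.74 (SE 0.07). Of 48 ribosome biogenesis genes 11 rose, 15 fell and 22 did not pass (camera adjusted p = 0.89), and with library totals 7 rose and 24 fell. Of these, 15 rose and 7 fell in replicates 1 and 2 alone (adjusted p = 0.17), against 10 and 19 in replicates 3 to 5 alone (adjusted p = 0.47). Their interaction passed at the preset correlation (adjusted p = 1.7e-06) and not with an estimated one (adjusted p = 0.88).

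Of 88 splicing factors and regulators 33 rose, 20 fell and 35 did not pass, with a median of 0.10 (camera adjusted p = 0.20, and adjusted p = 0.96 with an estimated correlation), and with library totals 18 rose and 33 fell. The kinases CLK1 and CLK3, which phosphorylate SR splicing factors, rose by 1.60 (SE 0.09) and 1.66 (SE 0.15). RBM20, a regulator of titin splicing, rose by 1.30 (SE 0.10). In replicates 1 and 2 alone the splicing list was called upward (adjusted p = 0.015), and in replicates 3 to 5 alone it was not (adjusted p = 0.61). The interaction with the replicate set passed at the preset correlation (adjusted p = 3.5e-05) and not with an estimated one (adjusted p = 0.70).

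**Figure D3:**
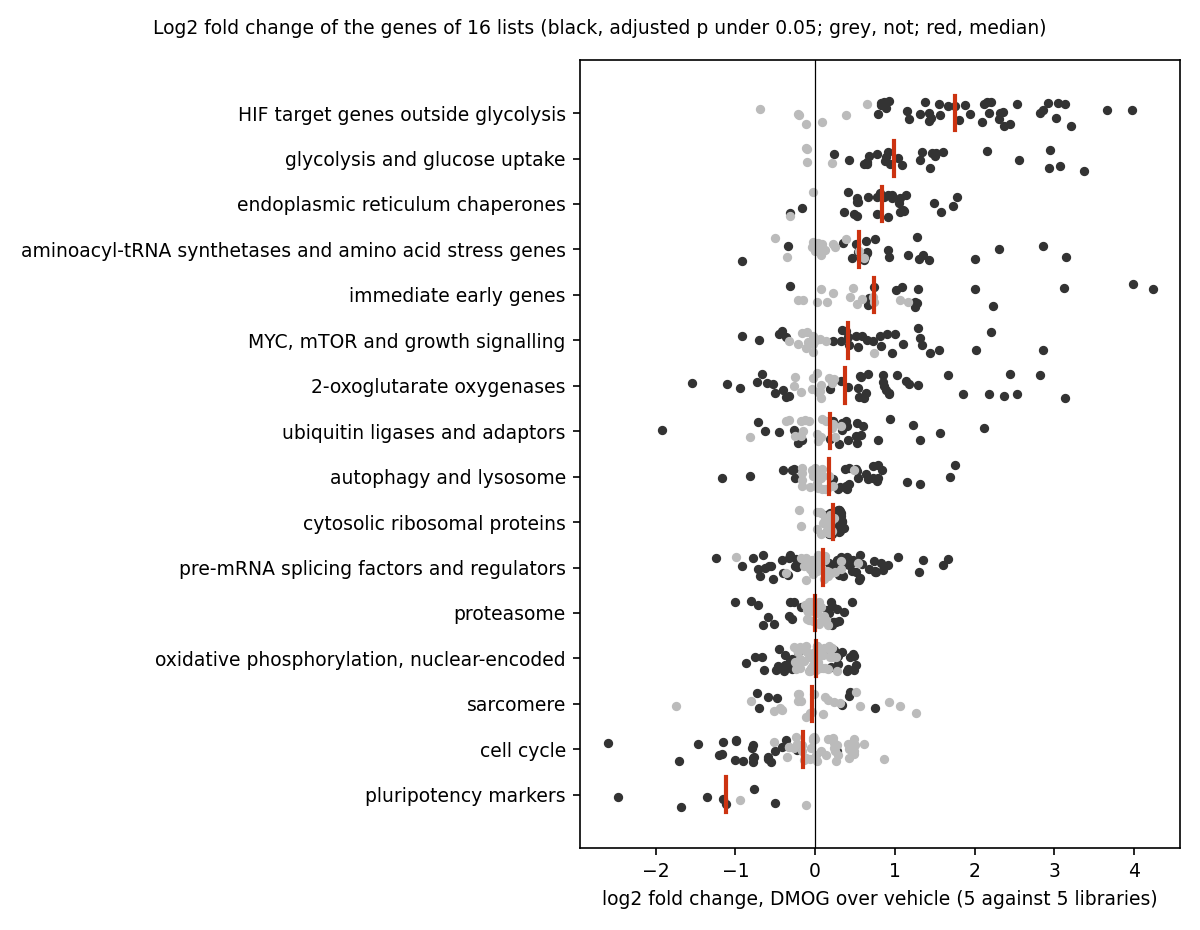
Log2 fold change, DMOG over vehicle, of the genes of 16 lists. Each point is a gene, black at an edgeR adjusted p under 0.05 and grey otherwise, and the red bar is the median, which lay at 1.76 for HIF targets outside glycolysis and at -1.12 for pluripotency markers; with library totals the median of ribosomal proteins fell from 0.22 to 0.00 and those of ubiquitin ligases and autophagy genes lay below 0.

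Cardiac gene lists were not called as a whole. Of 31 sarcomere genes 4 rose, 4 fell and 23 did not pass (camera adjusted p = 0.74, and adjusted p = 0.99 with an estimated correlation). The atrial light chain MYL4 fell by 0.70 (SE 0.12) and MYL3 by 0.59 (SE 0.11), while MYOZ2, a Z-disc protein, rose by 0.44 (SE 0.11), a call lost with library totals (0.21, adjusted p = 0.097, with 3.2e-04 to 0.097 over all alternatives). With library totals 1 sarcomere gene rose and 14 fell. In replicates 1 and 2 alone the sarcomere list was called downward (adjusted p = 0.024), and in replicates 3 to 5 alone it was not (adjusted p = 0.77), with an interaction that passed at the preset correlation (adjusted p = 8.4e-08) and not with an estimated one (adjusted p = 0.70). Of 33 ion channel and calcium handling genes 3 rose, 11 fell and 19 did not pass (camera adjusted p = 0.36), and with library totals 2 rose and 14 fell. KCNIP2, a potassium channel subunit, fell by 1.29 (SE 0.12) and the calcium channel CACNA1G by 1.24 (SE 0.17). Of 22 cardiac transcription and secreted factors 8 rose, 4 fell and 10 did not pass (camera adjusted p = 0.66), and with library totals 5 rose and 5 fell. SMYD1, a muscle methyltransferase, fell by 1.33 (SE 0.10), and GATA6 rose by 0.94 (SE 0.13).

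Of 78 nuclear-encoded genes of oxidative phosphorylation 16 rose, 15 fell and 47 did not pass (camera adjusted p = 0.89), and with library totals 5 rose and 36 fell. SDHC fell by 0.87 (SE 0.12), while UQCRC2 rose by 0.47 (SE 0.06). Of 47 genes of the citric acid cycle and fatty acid oxidation 12 rose, 15 fell and 20 did not pass (camera adjusted p = 0.66), and with library totals 6 rose and 25 fell. ACADM, which oxidises medium-chain fatty acids, fell by 0.85 (SE 0.08), and CPT1B, which carries fatty acids into mitochondria, rose by 0.60 (SE 0.07). Of 30 cholesterol genes 9 rose, 5 fell and 16 did not pass (camera adjusted p = 0.73), against 7 and 12 with library totals. INSIG2 rose by 2.16 (SE 0.13) and PMVK fell by 1.79 (SE 0.11). Of 31 iron, haem and NRF2 target genes 10 rose, 7 fell and 14 did not pass (camera adjusted p = 0.81), against 5 and 12 with library totals. The transferrin receptor TFRC rose by 1.88 (SE 0.16) and NQO1 fell by 1.09 (SE 0.10).

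The cell cycle and pluripotency lists were called lower at the preset correlation and not with an estimated one. Of 62 cell cycle genes 1 rose, 22 fell and 39 did not pass, with a median of -0.15 (camera adjusted p = 0.0048, and adjusted p = 0.95 with an estimated correlation). E2F2 fell by 2.60 (SE 0.18), and RRM2, PCNA and MCM6, which act in DNA replication, by 1.71 (SE 0.13), 1.47 (SE 0.12) and 1.20 (SE 0.10). In replicates 1 and 2 alone 23 cell cycle genes rose and 26 fell, with a median of 0.08 and a camera direction of down (adjusted p = 0.43), against 0 and 35 in replicates 3 to 5 alone (adjusted p = 1.2e-05); the interaction passed at the preset correlation (adjusted p = 3.5e-05) and not with an estimated one (adjusted p = 0.90). Of 9 tested pluripotency markers 0 rose, 7 fell and 2 did not pass, with a median of -1.12 (camera adjusted p = 0.0043, and adjusted p = 0.11 with an estimated correlation). CRIPTO, DPPA4 and LIN28A fell by 2.47 (SE 0.29), 1.68 (SE 0.21) and 1.12 (SE 0.14). CRIPTO was low, with 86 to 826 counts in vehicle libraries and 19 to 57 in DMOG libraries. Of 40 histone genes 0 rose, 5 fell and 35 did not pass (camera adjusted p = 0.74), against 11 that rose and 13 that fell with the replicate block. A total of 18 histone genes rose and 10 fell in replicates 1 and 2 alone, and in replicates 3 to 5 alone 5 rose and 9 fell, with an interaction that passed at the preset correlation (adjusted p = 0.033) and not with an estimated one (adjusted p = 0.90). Of 29 p53 targets 8 rose, 4 fell and 17 did not pass (camera adjusted p = 0.98), and with library totals 2 rose and 8 fell.

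Markers of other cell types gave no call at the preset correlation apart from pluripotency. Of 14 fibroblast and stromal markers 1 rose, 3 fell and 10 did not pass (camera adjusted p = 0.37, adjusted p = 0.96 with an estimated correlation, and adjusted p = 0.024 downward in replicates 1 and 2 alone). Of 9 endothelial markers 2 rose, 3 fell and 4 did not pass (adjusted p = 0.62). Of 10 smooth muscle markers 0 rose, 3 fell and 7 did not pass (adjusted p = 0.057). The smooth muscle list passed downward with the replicate block (adjusted p = 0.035), in replicates 1 and 2 alone (adjusted p = 6.3e-04), and without vehicle replicate 1, vehicle replicate 2, DMOG replicate 4 or DMOG replicate 5 (adjusted p = 0.042, 0.043, 0.035 and 0.024). It was not called with an estimated correlation (adjusted p = 0.50, and adjusted p = 0.27 with the block added). The interactions of the stromal and smooth muscle lists with the replicate set passed at the preset correlation (adjusted p = 0.032 and 0.03) and not with an estimated one (adjusted p = 0.90 each). LMOD1, a smooth muscle actin regulator, fell by 1.5 (SE 0.09), and NOS3, the endothelial nitric oxide synthase, by 2.10 (SE 0.16). Of 9 epicardial markers KRT19 rose, by 2.35 (SE 0.19), 0 fell and 8 did not pass (adjusted p = 0.66). Of 13 endoderm and hepatic markers 0 rose and 0 fell by edgeR, also at an unadjusted p under 0.05, by DESeq2 and by limma-voom (camera adjusted p = 0.66, and adjusted p = 0.99 with an estimated correlation). In replicates 1 and 2 alone 12 of them rose (adjusted p = 0.026), and the interaction with the replicate set did not pass (adjusted p = 0.71). Of 9 neural markers 1 rose, 2 fell and 6 did not pass (adjusted p = 0.55). Of 50 collagen and extracellular matrix genes 4 rose, 4 fell and 42 did not pass (adjusted p = 0.89), against 3 and 12 with library totals. LOX rose by 2.35 (SE 0.42) and TIMP3 fell by 1.14 (SE 0.14).

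In all, 10 lists were called higher and 2 lower at the preset correlation, and 2 higher and 0 lower with an estimated correlation. The response of a list differed between the replicate sets for 13 of 33 lists at the preset correlation and for 0 with an estimated one (lowest adjusted p = 0.70). Those not given above were 2-oxoglutarate oxygenases (adjusted p = 0.0073), heat shock genes (0.0097), oxidative phosphorylation (0.03), extracellular matrix (0.03), immediate early genes (0.033) and MYC, mTOR and growth signalling (0.047). With the replicate block the genes that rose and fell numbered 23 and 2 for immediate early genes, 12 and 11 for extracellular matrix, 7 and 9 for sarcomere, 6 and 13 for ion channels, 11 and 8 for cardiac factors, 8 and 9 for p53 targets, 6 and 27 for the cell cycle, 22 and 11 for ubiquitin ligases, 25 and 4 for amino acid stress, 42 and 1 for HIF targets, 1 and 9 for stromal, 1 and 4 for smooth muscle, 2 and 1 for epicardial and 2 and 4 for neural markers. With library totals the list counts not given above that moved by over 1.5 times were 24 and 3 for glycolysis, 40 and 1 for HIF targets, 13 and 2 for immediate early genes, 0 and 27 for the cell cycle, 0 and 8 for histones, 0 and 6 for stromal and 1 and 4 for neural markers. Adjusted over the list alone, member counts were as above except for ribosomal proteins (64 rose), aminoacyl-tRNA synthetases and amino acid stress genes (23 rose), ubiquitin ligases (21 rose), 2-oxoglutarate oxygenases (12 fell), ion channels (10 fell), histones (3 fell), sarcomere (3 rose), stromal markers (0 rose), oxidative phosphorylation (12 rose and 12 fell) and extracellular matrix (3 rose and 3 fell). Where a list count was 0, edgeR at an unadjusted p under 0.05, DESeq2 and limma-voom gave 0 as well, apart from histones that rose (1, 3 and 0). Median, mean and camera direction differed in sign for oxidative phosphorylation (0.01, -0.02 and down), ribosome biogenesis (-0.02, 0.01 and up), histones (0.05, -0.04 and down) and p53 targets (0.04, 0.06 and down).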

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

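A screen for a library far from the other 4 of its group covered 310 groups of values, the log2 CPM of the named genes and the totals, TMM factors and top-10 shares of the libraries. A gap to the nearest library of more than 0.71 of the group's range was found in 17 of them (5.48%), where chance gives about 1 in 20. DMOG replicate 3 was the library in 8 of the 17. In it the log2 CPM of HIF1A lay at 7.38 against 7.63 to 7.68 in the other DMOG libraries (gap ratio 0.833), ATF4 at 8.27 against 8.56 to 8.64 (0.784), CLK1 at 6.76 against 7.13 to 7.27 (0.725), MXD1 at 4.96 against 5.49 to 5.68 (0.736), MXI1 at 7.81 against 8.09 to 8.19 (0.737), RBM39 at 7.56 against 7.77 to 7.84 (0.75), MAP2 at 3.78 against 4.08 to 4.19 (0.732) and ETFB at 5.79 against 5.36 to 5.48 (0.721).

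Other DMOG libraries stood apart for WSB1 (9.0 in replicate 4 against 9.17 to 9.2, gap ratio 0.85), VWA5A (2.66 in replicate 5 against 2.94 to 3.01, 0.8), KCNIP2 (1.62 in replicate 5 against 2.01 to 2.14, 0.75), RPL21 (5.6 in replicate 1 against 5.76 to 5.81, 0.762), ASPH (9.11 in replicate 2 against 8.93 to 8.98, 0.722) and MCM6 (5.25 in replicate 2 against 4.97 to 5.05, 0.714). Among vehicle libraries, FOS lay at 4.23 in replicate 5 against 3.55 to 3.67 in the others (0.824), and MXI1 at 6.0 in replicate 3 against 5.84 to 5.88 (0.75). The total of vehicle replicate 2 was 196387627 counts against 49612417 to 81838820 in the others (gap ratio 0.781).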

How the results depend on the processing

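The use of every transcript row or of the lowest row of a gene, library totals, the replicate sets alone, libraries thinned to the smallest total, called lists without their HIF targets, and the block with an estimated correlation were chosen after the data were seen. Gene counts stayed within 1.5 times the counts reported under stricter filtering, DESeq2 size factors, upper quartile scaling, DESeq2, limma-voom, the lowest row of a gene and each replicate set alone. Leaving out 1 library gave 7443 to 8144 changed genes (3705 to 4089 higher, 3738 to 4079 lower), 10 to 11 lists higher, 2 to 3 lower, and a difference in the top-10 share of 1.25 to 1.41 percentage points. With the replicate block 9546 genes were called (4680 higher, 4866 lower), 8029 of the 8128 among them, and 13 lists. Among named genes the block added CALD1, TBX18, SEMA3D and OTX2 and removed none. Of these, CALD1 (-0.41, edgeR adjusted p = 0.0033) and SEMA3D (0.47, adjusted p = 0.0019) were also called in replicates 1 and 2 alone. OTX2 (-0.74, adjusted p = 0.0071) was called in replicates 3 to 5 alone. Among lists the block added smooth muscle markers and changed no other call. The test against a fold change of 1.5 left 2073 genes (885 higher, 1188 lower), by its own construction. With every transcript row as a feature 15624 were called (7881 higher, 7743 lower), because more features were tested. Library totals gave 2316 higher and 6169 lower, a shift of all genes. Lists higher and lower numbered 2 and 0 with an estimated correlation, and 0 and 0 with the block added; replicates 1 and 2 alone gave 4 lists lower, and the cause was not tested. No named gene or list that was called changed its fitted or camera direction under any alternative. Some list medians did change sign. The cell cycle median was 0.08 in replicates 1 and 2, and with library totals those of ubiquitin ligases and autophagy were -0.04 and -0.05. Over all alternatives the adjusted p of the ribosomal protein list ran from 3.5e-07 to 0.95, autophagy 0.0047 to 0.41, ubiquitin ligases 0.0086 to 0.31, cell cycle 1.2e-05 to 0.95, translation factors 0.019 to 0.66, splicing 0.015 to 0.96, sarcomere 0.024 to 0.99, smooth muscle 6.3e-04 to 0.5, and HIF targets 1.7e-62 to 0.071. Of the named genes, VIM (0.55, adjusted p = 0.042) lost its call with library totals (0.32), upper quartile scaling (0.42), limma-voom (0.51) and without each of vehicle replicates 1, 2 and 5 and DMOG replicates 3, 4 and 5 (0.45 to 0.59), and kept it with the block (0.53, adjusted p = 4.3e-04) and in each replicate set. Using no filter on low counts left the same genes, as the filter removed 0, and tests nothing. The alternatives on mitochondrially encoded genes were not run, as no rows of them were analysed here. Thinning all libraries to the smallest total, 48601530 counts, left 8061 changed genes, 7973 of the 8128 among them, and changed no call of a list or named gene. Without their members in the HIF target list the oxygenases lost their call (adjusted p = 0.23), and amino acid stress, MYC and mTOR signalling, autophagy and, at the threshold, ubiquitin ligases stayed called at the preset correlation (0.0015, 0.0048, 0.03 and 0.05) and not with an estimated one (0.82, 0.26, 0.59 and 0.41). The simulation took the depth, replicate number and spread of these libraries together. Changes of 1.5 on the log2 scale were recovered for 95.5% of 67 genes and of 0.5 for 30.3% of 66. Far fewer genes were changed there than were called here, so recovery in these data can differ. Depths below the smallest total were not tried.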

Other observations

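Chosen only after results were seen were the count of shared genes as the measure of depth, the tests of cell composition behind the replicate sets and GJA5, the expression trend fitted without ribosomal proteins, the counts of splits per list, and the comparison of transcript rows; the replicate sets themselves were found in these data. Within genes, the share of reads on 1 transcript row relative to the highest row differed between DMOG and vehicle for 436 of 3453 genes (limma, adjusted over genes), and for 244 with the replicate block. Of the 436, 40 changed by more than 0.5 on the log2 scale, 20 with the row lower and 20 with it higher in DMOG, and 30 of the 40 were called with the block. Of 100 splits of the libraries, 1, the real one, gave as many as 436, and the highest other gave 3. This argues against chance only where libraries could be swapped freely. These splits ignore the pairing; of the 9 that part all pairs, too few for a share under 0.05, the others gave 0 by limma, with 73 to 290 genes at an unadjusted p under 0.05 against 862 for the real one. In SRSF3, a splicing factor, the coding row NM_003017 lay at 91.2% ± 1.03 (SD, n = 5) of the non-coding row NR_036610 in vehicle and 78.6% ± 1.91 in DMOG, a log2 change of -0.21 (SE 0.02) and so below that size. In WTAP, a subunit of the RNA methylation complex, the row NM_001270533 went from 54.1% ± 3.64 to 28.9% ± 2.43 of NM_004906, a log2 change of -0.90 (SE 0.07). Rows share reads, so these are ratios of row counts and not isoform fractions.

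The libraries numbered 3 to 5 differed from those numbered 1 and 2 in 5762 genes in a model with treatment (2796 higher, 2966 lower). Higher in 3 to 5 were the heat shock gene HSPA6 (log2 difference 5.56, SE 0.51), the natriuretic peptides NPPB (3.94, SE 0.52) and NPPA (3.25, SE 0.27), the actin ACTA1 (3.82, SE 0.24) and WT1 (3.23, SE 0.40). Higher in 1 and 2 were KRT23 (-3.93, SE 0.36), CYP19A1 (-3.80, SE 0.48), TFAP2A (-2.91, SE 0.29) and GRHL2 (-2.88, SE 0.32). These genes were named after their values were seen. Among the fixed lists, the smallest camera p in 3 to 5 against 1 and 2 belonged to histones, p53 targets and the cell cycle. Of 40 histones 38 were lower and 0 higher, and of 62 cell cycle genes 50 were lower and 2 higher. Of 29 p53 targets 23 were higher and 0 lower. Camera called these lists at the preset correlation and not with an estimated one (adjusted p = 0.51, 0.51 and 0.23). The DMOG response differed between the sets for 628 genes, among them BHLHE40 (difference -1.47, SE 0.14), NES (1.23, SE 0.14) and TRIM55 (1.20, SE 0.14). It differed for 9 of the genes the naming rule takes. VEGFA (-0.92, adjusted p = 0.0076), CLK3 (-0.67, adjusted p = 0.0082), NR4A1 (-2.22, adjusted p = 0.027), PFKFB3 (-0.59, adjusted p = 0.033) and EGLN2 (-0.45, adjusted p = 0.045) rose less in 3 to 5, and MYL4 (0.68, adjusted p = 0.015) and MYL3 (0.54, adjusted p = 0.039) fell less. S100A4 fell more in 3 to 5 (-0.89, adjusted p = 0.041). For SNAP25 the difference was 1.12 (adjusted p = 0.045). It rose by edgeR in 3 to 5 alone (adjusted p = 2.0e-04) and lost its call in 1 and 2 alone (0.33, adjusted p = 0.15). Of the 10 ways to part the 5 numbers into 2 and 3, only this one (1 of 10) called 5762 genes, against at most 357 for the others, and only this one (1 of 10) called 628 interactions, against at most 1. With 10 ways the share cannot go under 0.05.

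After all libraries were thinned to the smallest total, 5559 of the 5762 genes (96.5%) were still called in the same direction, which argues against depth as the cause of these sets. Fewer cardiomyocytes in one set, with the other cell types unchanged relative to each other, would raise the markers of all of those there. In numbers 4 and 5 against 1 and 2, all 13 endoderm and hepatic markers were lower by edgeR (median -1.55, quartiles -1.80 and -1.04). Of 9 epicardial markers 7 were higher and 1 lower (median 1.69). Library means of both lists did not overlap in either group, which argues against fewer cardiomyocytes alone as the whole cause there. Camera called neither list with an estimated correlation (adjusted p = 0.35 and 0.40). A joint shift of several cell types cannot be separated by these lists. Of 31 sarcomere genes, the cardiomyocyte list, 10 were higher and 4 lower (median 0.20, camera adjusted p = 0.0084, and adjusted p = 0.77 with an estimated correlation). In number 3, with 1 library per group, the endoderm median was -0.30, the epicardial 1.00 and the sarcomere 0.16. The mean log2 CPM of endoderm markers was 6.89 in vehicle, against 6.75 and 6.82 in 1 and 2. In DMOG it was 6.71, against 7.28 and 7.31, the opposite direction. Sarcomere means were higher in number 3 in vehicle (8.07 against 8 and 7.93) and in DMOG (8.27 against 7.6 and 7.52). With 1 library per group these values do not settle the share of cardiomyocytes there, which stays open. Separate differentiations or days remain open, since the labels give none, and no other explanation was tested.

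Of 100 splits of the 10 libraries, 1, the real one, gave as many as the 8128 changed genes. The highest other, with 1264 genes, set vehicle replicates 1, 2 and 3 and DMOG replicates 1 and 2 against the rest. That split followed the replicate sets. It was the only other split (1) to call any gene. All remaining splits called 0, those that balance the replicate sets among them. The count of splits argues against chance only where libraries could be swapped freely, as these splits ignore the pairing. Of the 9 drawn splits that part all pairs, the others called 0 genes by edgeR, with 7 to 3812 genes at an unadjusted p under 0.05 against 8830 for the real one; 9 are too few for a share under 0.05. The 12 called lists did not exceed other splits, as 78 of 100 gave as many, up to 21, so chance is not excluded for their number at the preset correlation. For single lists, a p as small came from 1 of 100 splits for HIF targets, glycolysis, 2-oxoglutarate oxygenases and MYC and mTOR signalling, 3 for ubiquitin ligases and 4 for endoplasmic reticulum chaperones. It came from 16 for pluripotency markers, 23 for autophagy, 33 for immediate early genes, 34 for amino acid stress genes, 46 for ribosomal proteins and 59 for the cell cycle. Of the 9 drawn splits that part all pairs, only the real one (1 of 9) gave a p as small for immediate early genes and the 6 lists with 1 to 4 of 100, 2 did for autophagy and 4 for each of pluripotency markers, amino acid stress genes, ribosomal proteins and the cell cycle, and 6 called as many lists.

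The rise of ribosomal protein mRNAs may reflect a trend with expression level. A trend with transcript length is argued against, since removing it left a median of 0.31 (95% bootstrap interval 0.28 to 0.34, 75 genes). Removing the trend with expression level left -0.03 (-0.05 to -0.02), and -0.03 (-0.05 to -0.01) where the trend was fitted to the other genes alone, so these genes rose no more than others of like abundance. These intervals resample genes and not libraries, and take the genes as independent. The estimated inter-gene correlation of the list was 0.51, so the intervals are too narrow and leave out the spread between libraries. The choice of scaling shifts all genes alike. The median of the list went from 0.22 with TMM to 0.09 with upper quartile scaling and 0 with library totals. It stayed 0.21 above the median of all genes. The size of the rise thus depends on the scaling, while the distance of the list from all genes does not. A change in total mRNA per cell stays open, as no spike-in was analysed here.

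GJA5 fell by 3.98 on the log2 scale. Fewer endothelial cells would lower their markers by about as much if they were the source of its mRNA. Of 9 such markers 3 fell (NOS3 at -2.10, ENG at -1.72 and KDR, the most abundant, at -0.99), 2 rose (FLT1 at 1.24 and EGFL7 at 0.92) and the median was -0.21 (95% bootstrap interval -1.72 to 0.92). Of 14 atrial markers other than GJA5, 8 of them in another list, 4 fell (CHRM2 at -0.98, CACNA1D at -0.92, KCNJ5 at -0.72 and MYL4 at -0.70), 2 rose (SLN at 1.29 and STARD10 at 0.77) and the median was -0.16 (-0.59 to 0.61), with the most abundant, MYL7, at -0.42 (edgeR adjusted p = 0.15). Both intervals lie above -3.98, but they resample marker genes and not libraries. The endothelial markers CDH5, ESAM and TIE1 lay at a low log2 CPM of 1.56, 1.05 and 1.02. A change of the markers within cells cannot be told apart from a loss of cells. Markers of each type both rose and fell, so they cannot all have kept their level per cell. The values therefore do not decide whether loss of either cell type, in whole or in part, lowered GJA5. Markers outside the naming rule were named after their values were seen. That DMOG lowers GJA5 within cardiomyocytes is a hypothesis these bulk data leave untested.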
